A study of Arabidopsis thaliana with 16 samples.

How the data were processed

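RNA was measured by sequencing in 16 libraries of Arabidopsis thaliana Col-0 seedlings aged 6 days, grown on agar medium in continuous white light at 22 °C. The labels give 4 genotypes (WT, the mutant pif4, the double mutant mrg1 mrg2 and the triple mutant), each kept at 22 °C or treated at 28 °C for 3 h, with 2 libraries per group. Per the labels, RNA came from whole seedlings, was extracted with a Tiangen plant kit, and was made into libraries with a stranded kit for mRNA from Kapa Biosystems. The labels do not say whether the 2 libraries of a group came from separate cultures, so every p-value given here measures only the spread between libraries.

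The deposited table holds raw counts per gene, with no normalization by the authors, for 33602 genes identified by their TAIR gene IDs. The authors' processing notes name cutadapt, HISAT2, SAMtools and featureCounts, with the genome build TAIR10. Versions, options, annotation and the strand setting of the counting are not given in the sources used here. Reads that overlap a gene on the other strand and reads shared by near-identical gene copies can therefore not be traced. All values in the table were whole numbers, 0 lines lacked a gene and 0 sample columns were left unused. Gene symbols, products and positions came from reference tables for TAIR10.1, in which 32835 of the IDs had an entry.

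Library totals ran from 7186066 to 11363353 counts. A floor of 3 counts per library corresponds to 0.264 to 0.417 CPM (counts scaled to the library total), below which expression was not detectable at this depth. Intervals on ratios of reads are exact binomial intervals at 95% and, like the floors, cover counting error only.

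Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 8 groups (min.count 10, min.total.count 15), which left 20075 genes tested. Normalization was by TMM. All 16 libraries entered 1 quasi-likelihood fit (glmQLFit with legacy = FALSE) with 8 groups and no replicate term, which left 8 residual degrees of freedom. The prior degrees of freedom were 29.1 and the common biological coefficient of variation was 5.74%. Each of 16 comparisons was tested with the two-sided quasi-likelihood F-test, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene is said to have risen, fallen or changed where its adjusted p was under 0.05. The 16 comparisons include 4 warm responses (28 °C against 22 °C within a genotype) and 6 comparisons of a mutant with WT at a temperature. The triple mutant was also set against mrg1 mrg2 and against pif4 at 28 °C. Tested too were 3 differences between a mutant's warm response and that of WT (interactions). The last comparison was the departure from additive effects at 28 °C on the log2 scale (mrg1 mrg2 pif4 minus mrg1 mrg2 minus pif4 plus WT).

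The 22 gene lists were written from textbook knowledge, and none was chosen on these samples. They are PIF4-linked growth genes, auxin biosynthesis, auxin response, brassinosteroid, gibberellin, heat shock, unfolded protein response, circadian clock, light signalling, flowering, anthocyanin and flavonoid, photosynthesis and chlorophyll, salicylic acid defence, touch and wounding, cold response, abscisic acid, cell wall loosening, chromatin factors, cell cycle, root markers, shoot meristem and epidermis markers, and seed storage. Some genes stand in more than 1 list: IAA19, IAA29 and SAUR22 are both PIF4-linked and auxin response genes, XTH15 and EXPA8 are both PIF4-linked and cell wall genes, and YUC8 is both PIF4-linked and an auxin biosynthesis gene. Each list was tested in each comparison with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 22 lists. The test was repeated with a correlation estimated from the residuals. Of the 352 list tests, 108 passed, and 51 of these calls hold with an estimated correlation. The text gives the p with an estimated correlation wherever a call was lost with it, and a list call given without that p holds. A call that holds can still have a far larger p with it. For the photosynthesis list these p ran from 0.00235 (pif4 against WT at 28 °C) to 0.0483 (mrg1 mrg2 against WT at 22 °C).

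Named genes followed a fixed rule. MRG1, MRG2 and PIF4 are always given. Among genes that changed, had non-overlapping libraries in the 2 groups compared (for an interaction, all that changed) and had a mean of at least 5 CPM in the higher group, the 10 largest changes per direction qualified in the WT warm response and the 5 largest per direction elsewhere. Up to 4 members of each list per comparison, by smallest p, qualified as well, and the text names a part of all these. MRD1, AT2G01422 and AT1G63540, with almost no reads in a group, are given as reads and ratios of reads. Other genes near the floor in a group, such as UGT73C1 in the mutants, are given as log2 changes or levels whose size rests on few reads. MRD1, AT2G01422, AT1G63540 and the genes called in the same direction in all 6 comparisons with WT were chosen after their values were seen.

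The fit, the threshold, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors (RLE) in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate term, only the compared groups in the fit, legacy = TRUE, and each library left out in turn. Chosen after seeing the data were a fit without organelle and rRNA genes, comparisons between the warm responses of the mutants, simulated interactions of unchanged mutants, and the tests of explanations in the closing section.

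Calls were tested on simulated data, built on the mean levels and the spread of these libraries. With 100 genes changed 1.5-fold and 100 changed 2-fold among 20075, the WT warm response recovered 40% and 74% of them, with 5 false calls among 119. The difference between the pif4 and WT warm responses recovered 27% and 59%, with 5 false among 91. The departure from additivity recovered 32% and 58%, with 15 false among 105. A list with changed members reached an adjusted p of 1.65e-68, and 0 of 100 random lists were called.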

Results

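Transcripts were counted in seedlings of 4 Arabidopsis genotypes at 2 temperatures. The genotypes were WT, the double mutant mrg1 mrg2, the mutant pif4 and the triple mutant mrg1 mrg2 pif4. MRG1 (AT4G37280) and MRG2 (AT1G02740) encode related chromodomain proteins that bind methylated histone H3, and PIF4 (AT2G43010) encodes a bHLH transcription factor that promotes elongation growth in warmth. Seedlings stayed at 22 °C or were given 3 h at 28 °C, which makes 8 groups of 2 libraries each. Totals per library ran from 7186066 counts in WT at 28 °C replicate 2 to 11363353 in mrg1 mrg2 at 28 °C replicate 1. The first principal component of log2 CPM held 31.5% of the variance and separated the 22 °C from the 28 °C libraries.

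In what follows, a ± after a log2 change is an approximate standard error. It is the size of the change divided by the square root of its edgeR F statistic. Where a group holds few reads it can be too small. A ± after a level in CPM is the SD of the group's libraries (n = 2). Replicate libraries differed by more than counting noise in every group, with a chi-square per gene of 1.83 to 4.47 at 22 °C and 7.84 to 9.72 at 28 °C. This value is a mean over genes that a few highly expressed ones can dominate, so it does not give the spread of a typical gene. Replicate 2 held a larger share of reads of the ribosomal RNA gene AT3G41768 than replicate 1 in all 8 groups. At 22 °C the shares were 8.17% against 7.97% in WT, 8.23% against 6.48% in mrg1 mrg2, 7.22% against 7.08% in pif4, and 7.29% against 5.66% in the triple mutant. At 28 °C they were 9.09% against 5.96% in WT, 9.18% against 5.83% in mrg1 mrg2, 8.64% against 5.57% in pif4, and 8.5% against 4.88% in the triple mutant.

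The mutated genes were compared first, to show what the genotype labels mean at the level of transcripts. MRG1 lies on chromosome 4 from 17546577 to 17549559, MRG2 on chromosome 1 from 599330 to 602199 and PIF4 on chromosome 2 from 17886101 to 17889087 (build TAIR10.1). MRG1 fell in mrg1 mrg2 against WT by 1.87 ± 0.17 on the log2 scale at 22 °C (adjusted p = 5.34e-11) and by 2.48 ± 0.17 at 28 °C (8.71e-14). MRG2 fell by 3.94 ± 0.33 at 22 °C (8.24e-12) and by 4.09 ± 0.35 at 28 °C (3.55e-11). In mrg1 mrg2 pif4, MRG1 fell by 2.17 ± 0.18 (5.24e-12) and 2.84 ± 0.18 (1.41e-14), and MRG2 fell by 5.17 ± 0.40 (1.29e-12) and 4.70 ± 0.38 (9.52e-12), at 22 and 28 °C. Each WT or pif4 library held 168 to 225 reads of MRG1 and 63 to 99 of MRG2, against 27 to 64 and 2 to 8 in each library of the genotypes labelled mrg1 mrg2.

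PIF4 transcript was not called lower than in WT in the genotypes labelled pif4. Its level was 27.9 ± 3.88 CPM in pif4 and 31.7 ± 2.97 in WT at 22 °C (log2 difference −0.18 ± 0.10, adjusted p = 0.302), and 78.2 ± 1.06 against 90.4 ± 5.82 at 28 °C (−0.21 ± 0.09, adjusted p = 0.319). In the triple mutant the levels were 38.3 ± 4.39 at 22 °C and 83.5 ± 1.96 at 28 °C (difference from WT at 28 °C −0.12 ± 0.09, adjusted p = 0.444). At 22 °C its difference from WT of 0.28 ± 0.10 passed narrowly (adjusted p = 0.0453, range over the alternatives 0.0196 to 0.45). That call was lost without WT at 22 °C replicate 2 (0.391), triple mutant at 22 °C replicate 2 (0.45), pif4 at 28 °C replicate 2 (0.0511), or triple mutant at 28 °C replicate 1 (0.0511) or replicate 2 (0.0509). MRG1 and MRG2 did not differ detectably between pif4 and WT: the differences were 0.12 ± 0.14 (adjusted p = 0.669) and −0.25 ± 0.20 (0.505) at 22 °C, and −0.06 ± 0.14 (0.935) and −0.08 ± 0.21 (0.94) at 28 °C.

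**Figure D1:**
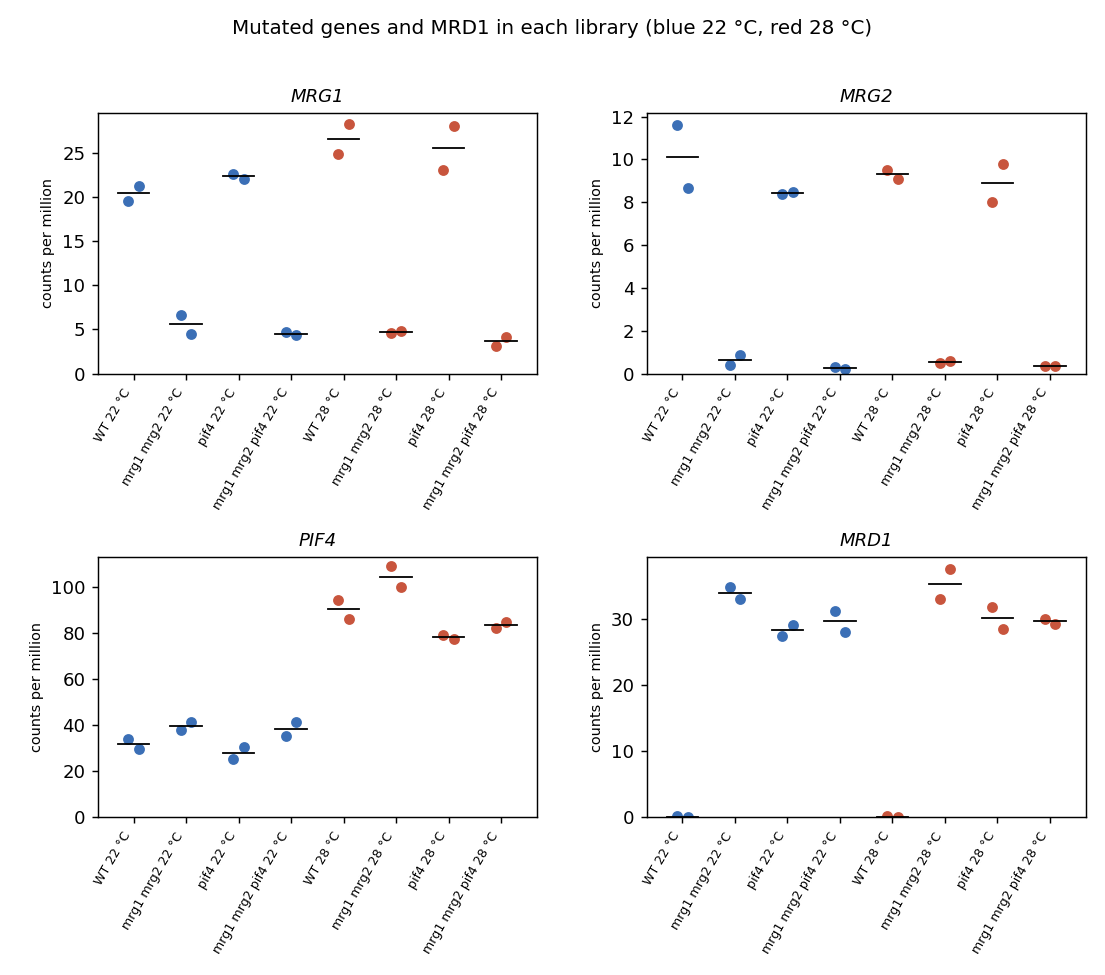
Levels of MRG1, MRG2, PIF4 and MRD1 in CPM (vertical axes) in each library (points) with group means (bars), for 4 genotypes at 22 °C (blue) and 28 °C (red). MRG1 and MRG2 are low in both genotypes labelled mrg1 mrg2, PIF4 is near WT levels in both genotypes labelled pif4, and MRD1 is near 0 in WT alone.

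The first comparison asks what 3 h at 28 °C did to seedlings with all 3 genes intact. Chaperone genes rose, and genes of cold protection and of anthocyanin and flavonoid synthesis fell. HSP70 (AT3G12580), a cytosolic chaperone, went from 36.1 ± 1.04 to 206 ± 0.804 CPM, a rise of 2.52 ± 0.08 (log2; adjusted p = 9.58e-24). HSP90.1 (AT5G52640), an inducible chaperone, rose by 2.12 ± 0.13 (1.77e-16), and HSP101 (AT1G74310), which dissolves protein aggregates, by 1.62 ± 0.13 (2.99e-13). IRT1 (AT4G19690), the main iron transporter of root epidermis, went from 30.7 ± 0.446 to 1.44 ± 0.616 CPM, a change of −4.36 ± 0.22 (2.73e-18). PIF4 itself rose by 1.52 ± 0.09 (4.14e-16).

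In all, 2666 genes rose and 2742 fell in WT at 28 °C, of which 286 and 537 changed at least 2-fold. Among the largest rises were the ER stress gene TIN1 (AT5G64510) (3.45 ± 0.39, adjusted p = 5.15e-09), the co-chaperone gene Hop3 (AT4G12400) (2.74 ± 0.11, 5.44e-21), the heat-response coactivator gene MBF1C (AT3G24500) (2.69 ± 0.12, 9.83e-20) and AT5G48570, an FKBP-type isomerase gene (2.74 ± 0.14, 2.26e-18). AT5G12110, which encodes a translation elongation factor 1-beta, rose by 2.75 ± 0.15 (1.74e-17). Of genes for late embryogenesis abundant proteins, known from drying seeds, AT3G15670 rose by 2.80 ± 0.33 (1.34e-08), AT3G53040 by 2.68 ± 0.23 (7.28e-12) and AT2G42560 by 2.48 ± 0.39 (5e-06). The largest falls included the glucosyltransferase gene UGT74E2 (AT1G05680) (−5.32 ± 0.39, 6.09e-14), CYP82C4 (AT4G31940), which acts in coumarin synthesis under iron shortage (−3.48 ± 0.39, 3.31e-09), and the glutathione transferase gene GSTU24 (AT1G17170) (−3.22 ± 0.17, 1.17e-17). UGT74E2 stood at 0.406 ± 0.242 CPM in WT at 28 °C, near the floor of 0.357 to 0.417 CPM of those libraries, so the size of its fall is uncertain. AT4G01870, a tolB-like protein gene, fell by 3.21 ± 0.12 (5.33e-22) and the nitrilase gene NIT4 (AT5G22300) by 3.09 ± 0.27 (1.37e-11). At 22 °C the means of UGT74E2, GSTU24, AT4G01870 and NIT4 were higher in WT than in every mutant. AT4G01870 stood at 113 CPM in WT against 17.3 to 25.4, and UGT74E2 at 16 against 3.25 to 4.57. How much of these falls reflects a departure of the WT group at 22 °C was not tested. Both libraries of one temperature lay above both of the other for each gene of this paragraph.

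Of 20 heat shock genes, 14 rose and 0 fell in WT (15 and 0 adjusted over the list alone; camera adjusted p = 8.96e-12). Of 19 PIF4-linked growth genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone; 6.7e-05). They included XTH15 (AT4G14130), which encodes an enzyme that remodels cell wall xyloglucan (1.27 ± 0.11, adjusted p = 2.18e-11), LNG2 (AT3G02170), which promotes lengthwise cell expansion (0.84 ± 0.08, 2.16e-10), the expansin gene EXPA8 (AT2G40610) (0.67 ± 0.08, 1.13e-08) and the auxin synthesis gene YUC8 (AT4G28720) (1.25 ± 0.31, 0.00198). Of 11 unfolded protein response genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 6.7e-05), among them the ER chaperone genes HSP90.7 (AT4G24190) (0.51 ± 0.05, adjusted p = 1.21e-10) and BIP1 (AT5G28540) (0.37 ± 0.05, 1.3e-06). Of 23 photosynthesis and chlorophyll genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 2.85e-23, adjusted p = 0.0295 with an estimated correlation). PORB (AT4G27440), for the light-dependent step of chlorophyll synthesis, rose by 0.93 ± 0.05 (2.19e-18) and LHCA4 (AT3G47470), for an antenna protein of photosystem I, by 0.80 ± 0.04 (8.97e-19). The 2 that fell, RBCS1A (AT1G67090) and RBCS1B (AT5G38430), encode near-identical small subunits of Rubisco whose reads are uncertain between copies.

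Of 14 anthocyanin and flavonoid genes, 0 rose and 10 fell in WT (0 and 10 adjusted over the list alone; camera adjusted p = 2.13e-09). CHS (AT5G13930), the entry enzyme of flavonoid synthesis, went from 373 ± 20.4 to 161 ± 3.59 CPM (−1.21 ± 0.06, adjusted p = 6.65e-19), and F3H (AT3G51240), a hydroxylase further along the pathway, fell by 1.93 ± 0.09 (1.39e-19). Of 11 cold response genes, 0 rose and 8 fell (0 and 8 adjusted over the list alone; camera adjusted p = 1.29e-08). KIN2 (AT5G15970) and RD29A (AT5G52310), which encode protective proteins made in cold and drought, fell by 1.94 ± 0.10 (5.43e-18) and 1.66 ± 0.10 (7.42e-16). Of 22 root markers, 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0068), led by IRT1 and by FRO2 (AT1G01580), the root ferric reductase gene (−2.42 ± 0.23, adjusted p = 4.89e-11). Clock genes went both ways, with 8 of 20 up and 7 down (camera adjusted p = 0.692). LHY (AT1G01060), a morning gene of the clock, fell by 1.88 ± 0.07 (1.57e-22), while LUX (AT3G46640), an evening gene, rose by 1.45 ± 0.09 (1.84e-15).

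The same question was put to mrg1 mrg2. Heat shock genes rose and several cold genes fell: HSP90.1 rose by 3.13 ± 0.14 (adjusted p = 2.61e-20), HSP70 by 2.96 ± 0.09 (1.98e-25) and MBF1C by 2.83 ± 0.13 (4.39e-20). ASN1 (AT3G47340), an asparagine synthetase gene known to respond to sugar and darkness, rose by 2.99 ± 0.09 (1.98e-25). IRT1 fell by 3.57 ± 0.18 (7.59e-19), CYP82C4 by 4.82 ± 0.36 (1.17e-13), COR15A (AT2G42540), a chloroplast protein gene of cold acclimation, by 2.94 ± 0.29 (1.31e-10) and RD29A by 1.81 ± 0.10 (9.72e-17). PIF4 rose by 1.40 ± 0.09 (1.85e-15). In this genotype 2574 genes rose and 2835 fell.

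Of 20 heat shock genes, 14 rose and 0 fell in mrg1 mrg2 (17 and 0 adjusted over the list alone; camera adjusted p = 2.99e-12). Of 19 PIF4-linked genes, 9 rose and 0 fell (12 and 1 adjusted over the list alone; 0.00022), among them XTH15 (1.04 ± 0.12, adjusted p = 1.64e-08), HFR1 (AT1G02340), a bHLH gene that limits PIF activity (1.28 ± 0.25, 0.000131), and the auxin-responsive repressor gene IAA29 (AT4G32280) (1.87 ± 0.39, 0.000286). Auxin response genes rose in 9 of 25 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00331). Gibberellin genes rose in 6 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone; 0.00329), with GA20OX2 (AT5G51810), a gibberellin synthesis gene, up by 2.44 ± 0.47 (adjusted p = 0.000109). Of 14 brassinosteroid genes 5 rose and 0 fell (camera adjusted p = 0.0052, adjusted p = 0.0872 with an estimated correlation), with CPD (AT5G05690), a synthesis gene, up by 0.77 ± 0.06 (adjusted p = 1.01e-12). Anthocyanin genes fell in 11 of 14 cases and rose in 0 (0 up and 13 down adjusted over the list alone; camera adjusted p = 2.99e-12), and cold genes fell in 7 of 11 and rose in 0 (0 and 7 adjusted over the list alone; 9.59e-07). For photosynthesis genes, 14 rose and 5 fell of 23 (15 and 5 adjusted over the list alone; 3.63e-05, adjusted p = 0.299 with an estimated correlation).

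Under the label pif4, the question is what remained of that response. Chaperone and seed storage genes rose. HSP90.1 rose by 3.09 ± 0.14 (adjusted p = 9.01e-20), HSP70 by 2.87 ± 0.08 (3.52e-25) and AT5G51440, an HSP20-like chaperone gene, by 3.57 ± 0.31 (1.24e-11). The cruciferin genes CRA1 (AT5G44120) and CRU3 (AT4G28520), for storage proteins of the seed, rose by 3.62 ± 0.26 (9.64e-14) and 4.62 ± 0.33 (3.61e-14). Reads of CRA1 numbered 289 to 406 in the pif4 libraries at 28 °C and at most 48 in any other library. In whole seedlings a larger share of seed tissue in that group cannot be told from a response to warmth. XTH15 rose by 0.64 ± 0.12 (6.33e-05) and PIF4 by 1.48 ± 0.09 (1.99e-15), while IRT1 fell by 3.54 ± 0.19 (1.68e-17), CHS by 0.66 ± 0.06 (1.98e-11) and KIN2 by 1.57 ± 0.11 (1.72e-14). In all 2654 genes rose and 2488 fell.

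In pif4, 15 of 20 heat shock genes rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.04e-12). Of 6 seed storage genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; 0.000155). Of 14 anthocyanin genes 0 rose and 10 fell (0 and 11 adjusted over the list alone; 1.65e-07), and of 11 cold genes 0 rose and 7 fell (0 and 7 adjusted over the list alone; 1.51e-05). Of 19 PIF4-linked genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.341). Photosynthesis genes rose in 16 of 23 cases and fell in 4 (16 and 4 adjusted over the list alone; 1.41e-09, adjusted p = 0.219 with an estimated correlation).

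The triple mutant was compared across temperatures in the same way. HSP90.1 rose by 3.23 ± 0.14 (adjusted p = 6.72e-20), HSP70 by 2.84 ± 0.09 (4.96e-25) and Hop3 by 2.79 ± 0.12 (1.13e-20). XTH15 rose by 1.03 ± 0.11 (3.54e-09), PIF4 by 1.12 ± 0.09 (1.06e-12) and PORB by 0.47 ± 0.05 (2.85e-10). IRT1 fell by 4.57 ± 0.21 (1.27e-19), FRO2 by 2.47 ± 0.20 (1.32e-12), F3H by 1.41 ± 0.09 (1.25e-15) and RBCS1A, with the doubt about its copies, by 0.72 ± 0.03 (7.55e-19). In all 2590 genes rose and 2871 fell. Heat shock genes rose in 15 of 20 cases and fell in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 1.04e-10), anthocyanin genes fell in 10 of 14 and rose in 0 (0 up and 11 down adjusted over the list alone; 6.04e-09), and cold genes fell in 8 of 11 and rose in 0 (0 and 8 adjusted over the list alone; 1.29e-06). The lists of PIF4-linked genes (4 up and 0 down of 19, 3 and 0 adjusted over the list alone; 0.159) and photosynthesis genes (7 up and 6 down of 23, 8 and 6 adjusted over the list alone; 0.747) did not pass.

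**Figure D2:**
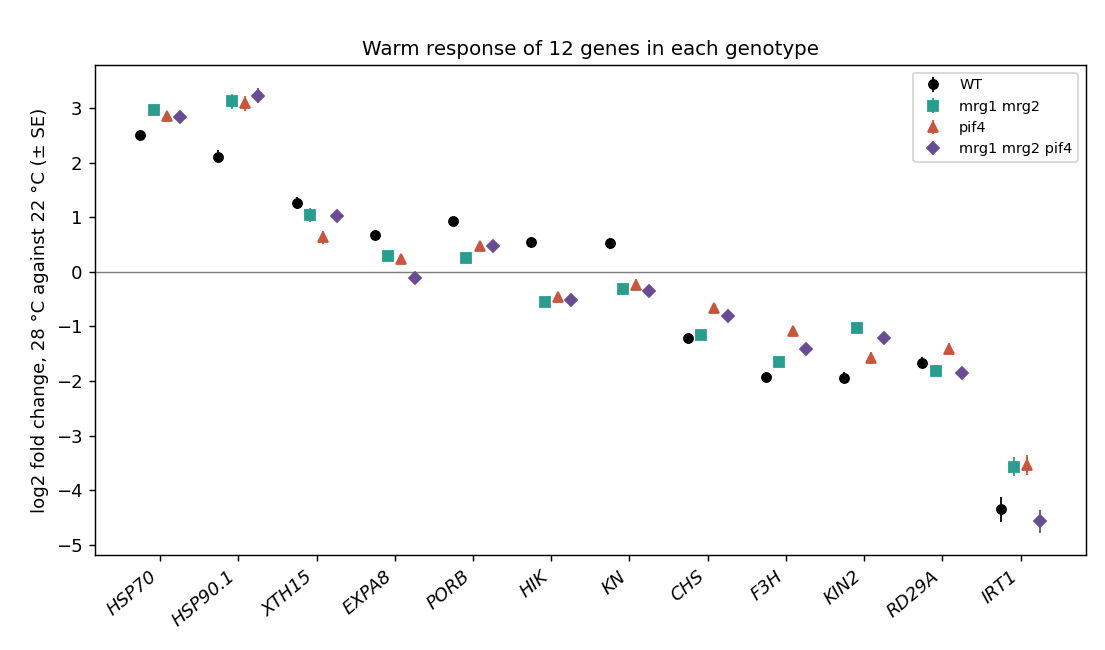
Log2 fold change at 28 °C against 22 °C (vertical axis, points with approximate standard errors from the F statistic) of 12 genes in each of 4 genotypes. HSP70 and HSP90.1 lie above 0 and CHS, F3H, KIN2, RD29A and IRT1 below 0 in every genotype, while HIK and KN lie above 0 in WT alone.

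The comparison of mrg1 mrg2 with WT at 22 °C asks what differs between these genotypes without warmth. Photosynthesis and cell division genes were higher and auxin response genes lower, as they were in pif4 against the same WT libraries, so these differences cannot be assigned to MRG1 and MRG2. ACC2 (AT1G36180), for a chloroplast acetyl-CoA carboxylase, stood at 73 ± 4.97 CPM against 11.4 ± 0.456 in WT, a rise of 2.67 ± 0.12 (adjusted p = 6.07e-19), and the transcription factor gene NAC103 (AT5G64060) rose by 2.42 ± 0.28 (9.16e-09). Among the falls were those of UGT73C1 (AT2G36750), a glucosyltransferase gene (−3.34 ± 0.46, 4.69e-07), FLA6 (AT2G20520), for a fasciclin-like arabinogalactan protein (−3.29 ± 0.41, 5.56e-08), and XTH13 (AT5G57540), another xyloglucan enzyme gene (−2.67 ± 0.33, 6.25e-08). HSP70 fell by 1.08 ± 0.09 (1.27e-11). In all 2469 genes rose and 2449 fell. PIF4 was higher by 0.33 ± 0.10 (adjusted p = 0.00991, range over the alternatives 0.00712 to 0.19), a call that was lost without WT at 22 °C replicate 2 (0.19) and without mrg1 mrg2 at 22 °C replicate 2 (0.13).

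Of 23 photosynthesis genes, 21 rose and 0 fell in mrg1 mrg2 at 22 °C (21 and 0 adjusted over the list alone; camera adjusted p = 1.54e-22). With an estimated correlation this call held narrowly (adjusted p = 0.0483). PORB rose by 0.86 ± 0.05 (adjusted p = 8.24e-17). Of 22 root markers 2 rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0448, range over the alternatives 0.032 to 0.11, adjusted p = 0.11 with an estimated correlation), a call lost without mrg1 mrg2 at 22 °C replicate 1 (0.0818). In whole seedlings a smaller share of root tissue cannot be told from changes within tissues. Of 11 cell cycle genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 1.29e-05): HIK (AT1G18370) and KN (AT1G08560), which act in building the new wall of dividing cells, rose by 0.92 ± 0.10 (adjusted p = 2.01e-09) and 0.86 ± 0.10 (1.42e-08). Of 25 auxin response genes 0 rose and 11 fell (0 and 12 adjusted over the list alone; camera adjusted p = 0.000389), among them the repressor genes IAA3 (AT1G04240) (−0.75 ± 0.11, adjusted p = 2e-06) and IAA2 (AT3G23030) (−0.57 ± 0.09, 6.47e-06). Clock genes fell in 7 of 20 cases and rose in 0 (0 up and 7 down adjusted over the list alone; camera adjusted p = 0.00138), GI (AT1G22770) by 0.53 ± 0.10 (adjusted p = 9.4e-05) and CHE (AT5G08330) by 0.56 ± 0.09 (1.35e-05). Of 19 cell wall genes 2 rose and 9 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.00266, adjusted p = 0.126 with an estimated correlation), with XTH24 (AT4G30270) down by 0.96 ± 0.07 (adjusted p = 3.48e-14).

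The same comparison for pif4 at 22 °C gave fewer calls, 1164 up and 1014 down. Photosynthesis and cell cycle genes were again higher and auxin response genes lower. The antenna gene LHCB2.2 (AT2G05070), whose reads are uncertain between near-identical copies, rose by 0.76 ± 0.04 (adjusted p = 2.52e-16), HIK by 0.90 ± 0.10 (8.22e-09) and KN by 0.77 ± 0.10 (3.91e-07). HEI10 (AT1G53490), which encodes a RING protein of meiotic crossing over, rose by 1.82 ± 0.31 (4.64e-05). UGT73C1 fell by 3.61 ± 0.49 (7.9e-07) and LOX2 (AT3G45140), for the first step of jasmonate synthesis in plastids, by 0.71 ± 0.07 (2.17e-09). IAA29 stood at 0.303 ± 0.429 CPM against 2.42 ± 0.215 in WT, with 1 library at 0 (−2.82 ± 0.63, adjusted p = 0.00165, range over the alternatives 6.41e-05 to 0.0561); the call was lost without pif4 at 22 °C replicate 1 (0.0561).

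Of 23 photosynthesis genes 20 rose and 0 fell in pif4 at 22 °C (21 and 0 adjusted over the list alone; camera adjusted p = 4.69e-62), and of 11 cell cycle genes 7 rose and 0 fell (9 and 0 adjusted over the list alone; 4.67e-08). Of 25 auxin response genes 0 rose and 6 fell (0 and 7 adjusted over the list alone; 0.00128), including IAA2 (−0.43 ± 0.09, adjusted p = 0.000702). Cold genes fell in 8 of 11 cases and rose in 1 (1 up and 8 down adjusted over the list alone; camera adjusted p = 2.31e-07), among them KIN2 (−0.77 ± 0.09, adjusted p = 7.68e-08). Touch and wounding genes fell in 4 of 21 cases and rose in 0 (1 up and 12 down adjusted over the list alone; camera adjusted p = 1.18e-05). Anthocyanin genes fell in 4 of 14 cases and rose in 0 (0 and 4 adjusted over the list alone; 0.0015, adjusted p = 0.0844 with an estimated correlation), CHS by 0.60 ± 0.06 (adjusted p = 4.59e-10). The total of 2178 genes was 1386 without WT at 22 °C replicate 1, 1305 without WT at 22 °C replicate 2 and 1234 without pif4 at 22 °C replicate 2.

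In mrg1 mrg2 pif4 at 22 °C, 1578 genes rose and 1515 fell against WT. PORB rose by 0.81 ± 0.05 (adjusted p = 4.46e-16), LHCB2.2 by 0.73 ± 0.04 (4.95e-16) and HIK by 0.58 ± 0.10 (3.45e-05), as did GH9B15 (AT4G23560), a cellulase-family gene, by 3.80 ± 0.41 (4.67e-09). UGT73C1 fell by 3.09 ± 0.44 (1.88e-06), LOX2 by 0.72 ± 0.07 (1.04e-09), IAA2 by 0.57 ± 0.09 (1.16e-05) and IAA3 by 0.52 ± 0.11 (0.00059). Of 23 photosynthesis genes 18 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 8.48e-38), and of 25 auxin response genes 0 rose and 6 fell (0 and 7 adjusted over the list alone; 0.00281). With an estimated correlation the adjusted p was 0.0393 for each of these lists. The total of 3093 genes was 1972 without WT at 22 °C replicate 1, 1957 without WT replicate 2, 2029 without triple mutant replicate 1 and 2007 without triple mutant replicate 2 of that temperature.

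At 28 °C several cell wall, growth and auxin genes were lower in mrg1 mrg2 than in WT. XTH24, which encodes another xyloglucan enzyme, stood at 151 ± 5.09 CPM against 284 ± 13.2 in WT (−0.91 ± 0.06, adjusted p = 8.71e-14), and XTH4 (AT2G06850), of the same family, fell by 0.66 ± 0.05 (5.78e-13). XTH15 fell by 0.80 ± 0.11 (1.22e-06), LNG2 by 0.42 ± 0.08 (0.000298) and EXPA8 by 0.40 ± 0.08 (0.000314). IAA3 fell by 0.62 ± 0.11 (0.000136) and IAA2 by 0.39 ± 0.09 (0.00204). HSP70 fell by 0.63 ± 0.07 (5.98e-08) and HSP101 by 0.80 ± 0.11 (3.38e-06). Of the heat shock list 0 of 20 genes rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.047, range over the alternatives 0.0281 to 0.192, adjusted p = 0.127 with an estimated correlation). That call was lost without any 1 library other than WT or pif4 at 28 °C replicate 2, up to 0.192 without WT at 28 °C replicate 1. LDOX (AT4G22880), for a late enzyme of the pathway, rose by 1.48 ± 0.26 (0.000102), DFR (AT5G42800), for the step before it, by 1.36 ± 0.28 (0.000539), and AT5G61160, for an anthocyanin acyltransferase, from 0.334 ± 0.14 to 8.07 ± 1.95 CPM (4.61 ± 0.45, 7.37e-10). The WT level of AT5G61160 lies below the floor of 0.357 to 0.417 CPM of those WT libraries, so the size of its rise is uncertain. Of 14 anthocyanin and flavonoid genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0488, range 0.0296 to 0.317, adjusted p = 0.317 with an estimated correlation). This call was lost without any 1 library other than mrg1 mrg2 at 28 °C replicate 2, up to 0.138.

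PIF4 in mrg1 mrg2 at 28 °C stood at 105 ± 6.31 CPM against 90.4 ± 5.82 in WT (0.21 ± 0.09, adjusted p = 0.0964, range over the alternatives 0.0235 to 0.446), and passed without organelle and rRNA genes (0.0235). In all, 1344 genes rose and 1486 fell. Of 19 PIF4-linked genes 0 rose and 5 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.00315, adjusted p = 0.0876 with an estimated correlation). Of 25 auxin response genes 0 rose and 5 fell (0 and 6 adjusted over the list alone; 0.0119, adjusted p = 0.0876 with an estimated correlation). Of 19 cell wall genes 1 rose and 5 fell (1 and 7 adjusted over the list alone; 9.96e-05, adjusted p = 0.113 with an estimated correlation). Of 23 photosynthesis genes 6 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.824). The total of 2830 genes was 1570 without WT at 28 °C replicate 2 and 1850 without mrg1 mrg2 at 28 °C replicate 2.

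The comparison of pif4 with WT at 28 °C gave the fewest calls of the 16, 235 up and 85 down, and PIF4-linked and auxin genes were among those that fell. IAA29 stood at 0.979 ± 0.215 CPM against 5.27 ± 0.521 in WT (−2.39 ± 0.43, adjusted p = 0.000606). AT5G02540, for a dehydrogenase-like protein, fell from 30.4 ± 0.189 to 11.4 ± 0.603 CPM (−1.42 ± 0.15, 2.29e-08), and AT2G43620, for a chitinase-family protein, from 7.05 ± 0.997 to 0.998 ± 0.539 CPM (−2.89 ± 0.36, 9.84e-07). Seed genes were higher: CRU3 rose by 4.26 ± 0.32 (1.41e-11), CRA1 by 3.43 ± 0.27 (2.04e-11) and the seed protein gene M17 (AT2G41260) by 4.80 ± 0.41 (1.82e-10). LHCB2.2 rose by 0.38 ± 0.04 (1.68e-07) and LHCA1 (AT3G54890), another antenna gene, by 0.33 ± 0.05 (1.15e-05).

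Of 19 PIF4-linked genes 0 rose and 6 fell in pif4 at 28 °C (0 and 12 adjusted over the list alone; camera adjusted p = 5.88e-16). XTH15 fell by 0.63 ± 0.11 (adjusted p = 0.000353, range over the alternatives 5.06e-06 to 0.0508), HFR1 by 1.45 ± 0.30 (0.00282, range 7.68e-05 to 0.0967) and ATHB2 (AT4G16780), a shade-response homeobox gene, by 1.1 ± 0.21 (0.00154, range 0.000104 to 0.052). Single libraries ended these calls: XTH15 without pif4 replicate 1 (0.0508), HFR1 without WT replicate 1 (0.0785) or pif4 replicate 1 (0.0967), and ATHB2 without WT replicate 2 (0.052), all at 28 °C. Of 25 auxin response genes 0 rose and 4 fell (0 and 12 adjusted over the list alone; camera adjusted p = 2.57e-09), of 23 photosynthesis genes 17 rose and 0 fell (21 and 0 adjusted over the list alone; 1.32e-67), and of 6 seed storage genes 3 rose and 0 fell (5 and 0 adjusted over the list alone; 3.27e-10). No unfolded protein response gene passed alone (0 of 11, 0 up and 4 down adjusted over the list alone), and the list was lower as a whole (camera adjusted p = 1.33e-05). The total of 320 genes was 213 without WT replicate 1, 150 without WT replicate 2, 195 without pif4 replicate 1 and 176 without pif4 replicate 2 at 28 °C.

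**Figure D3:**
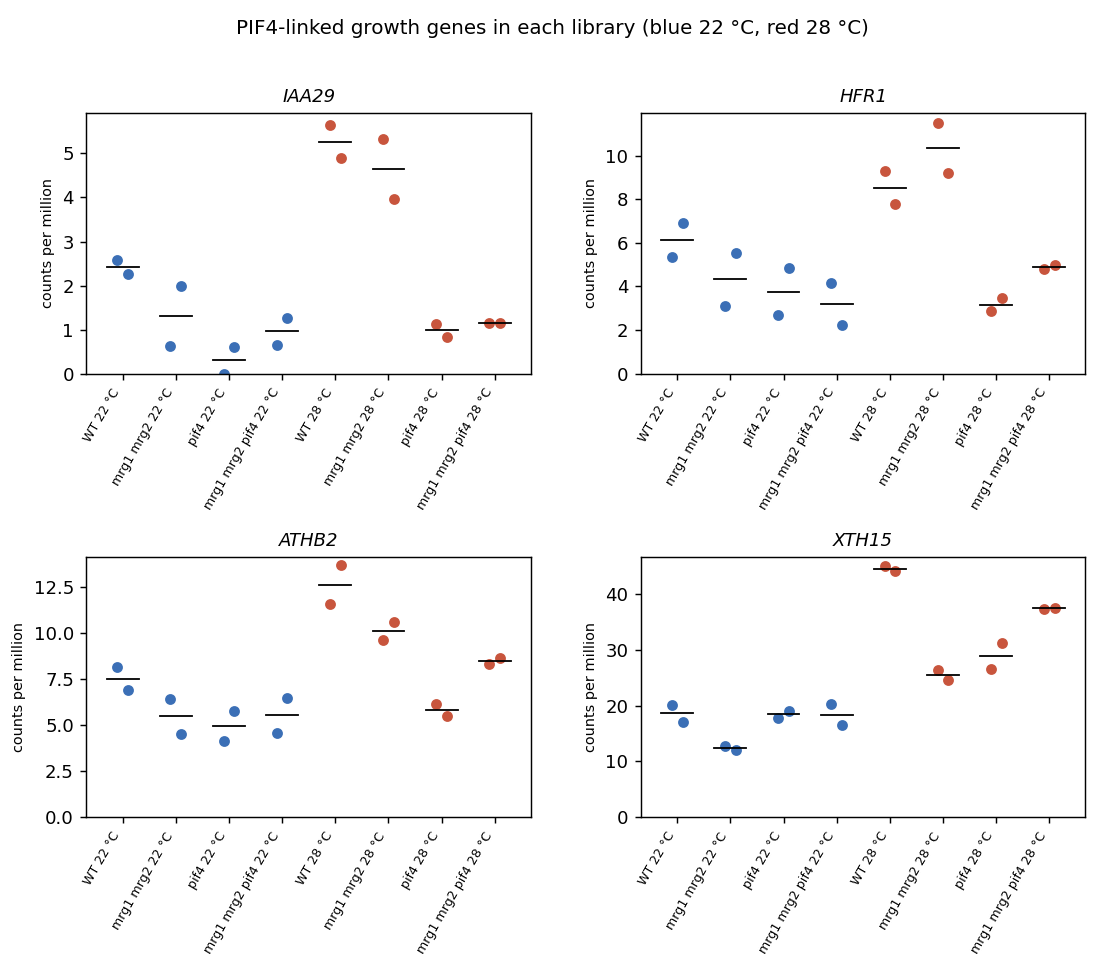
Levels of IAA29, HFR1, ATHB2 and XTH15 in CPM (vertical axes) in each library (points) with group means (bars), for 4 genotypes at 22 °C (blue) and 28 °C (red). At 28 °C the mean of IAA29 is 5.27 in WT and 0.979 in pif4, and that of XTH15 is 44.6 in WT, 25.5 in mrg1 mrg2, 29 in pif4 and 37.4 in mrg1 mrg2 pif4.

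In mrg1 mrg2 pif4 at 28 °C, PIF4-linked and auxin genes were lower than in WT as well. IAA29 fell by 2.21 ± 0.40 (adjusted p = 0.000139), EXPA8 by 0.73 ± 0.08 (7.69e-09), the homeobox gene HAT2 (AT5G47370) by 0.65 ± 0.12 (0.000212), LNG2 by 0.41 ± 0.08 (0.000404), IAA3 by 0.64 ± 0.11 (9.83e-05) and XTH4 by 0.54 ± 0.05 (1.2e-10). AT5G02540 fell by 1.85 ± 0.15 (7.2e-12) and HSP101 by 0.79 ± 0.11 (3.5e-06). BCB (AT5G20230), for a copper-binding protein of the cell surface, rose by 2.24 ± 0.26 (3.08e-08) and HEI10 by 2.08 ± 0.26 (1.5e-07). In all 1062 genes rose and 1315 fell. Of 19 PIF4-linked genes 0 rose and 9 fell (0 and 12 adjusted over the list alone; camera adjusted p = 7.94e-08), and of 25 auxin response genes 0 rose and 8 fell (0 and 10 adjusted over the list alone; 2.37e-06). Photosynthesis genes fell in 8 of 23 cases and rose in 2 (2 up and 11 down adjusted over the list alone; 6.95e-05, adjusted p = 0.397 with an estimated correlation), PORB being higher by 0.35 ± 0.05 (adjusted p = 6.23e-07). The total of 2377 genes was 1542 without WT replicate 1, 1402 without WT replicate 2, 1460 without triple mutant replicate 1 and 1456 without triple mutant replicate 2 at 28 °C.

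Set against mrg1 mrg2 at 28 °C, the triple mutant was used to ask what the label pif4 adds. The labels give no crosses, so other differences between the stocks cannot be told from effects of a label. This limit holds here, against pif4 and for additivity. AT2G01422, for example, held 316 reads in pif4 at 22 °C but 5 in the triple mutant. IAA29 was lower by −2.04 ± 0.39 (adjusted p = 0.000309), while XTH15 and XTH24 were higher by 0.55 ± 0.11 (0.000447) and 1.06 ± 0.06 (2.08e-15). The glutathione transferase gene GSTF6 (AT1G02930) stood at 5.63 ± 0.0664 CPM against 48.5 ± 7.71 (−3.11 ± 0.16, 3.36e-17), and NAC103 fell by 3.21 ± 0.36 (1.86e-08). DFR fell by 1.55 ± 0.26 (6.09e-05). THA1 (AT1G08630), for a threonine aldolase, rose by 2.62 ± 0.17 (1.97e-14), and PIF4 itself fell by 0.33 ± 0.09 (0.00828, range over the alternatives 8.84e-05 to 0.141), a call that was lost without mrg1 mrg2 replicate 1 (0.141) or triple mutant replicate 1 (0.0775) at 28 °C. In all 938 genes rose and 1060 fell, and PIF4-linked genes rose in 1 of 19 cases and fell in 4 (2 up and 9 down adjusted over the list alone; camera adjusted p = 0.0545). The total of 1998 genes was 1289 without mrg1 mrg2 replicate 1, 1313 without triple mutant replicate 1 and 1060 without triple mutant replicate 2 at 28 °C.

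Set next against pif4 at 28 °C, the same genotype was used to ask what mrg1 mrg2 adds. RBCS1A was lower by −0.63 ± 0.03 (adjusted p = 3.91e-16) and LHCA4 by −0.51 ± 0.04 (3.4e-12), and CRA1 fell by 3.39 ± 0.25 (9.29e-13). EXPA8 fell by 0.55 ± 0.08 (3.24e-06) and XTH4 by 0.40 ± 0.05 (1.03e-07). ACD6 (AT4G14400), a defence-related ankyrin gene, stood at 20.3 ± 2.32 CPM against 5.31 ± 0.49 (1.91 ± 0.16, 1.85e-11), and KIN2 rose by 1.03 ± 0.11 (6.22e-09). In all 680 genes rose and 1211 fell. Of 23 photosynthesis genes 0 rose and 19 fell (1 up and 20 down adjusted over the list alone; camera adjusted p = 3.33e-46), and of 6 seed storage genes 0 rose and 4 fell (0 and 4 adjusted over the list alone; 1.12e-05). The total of 1891 genes was 1221 without pif4 replicate 1, 1090 without pif4 replicate 2, 1125 without triple mutant replicate 1 and 1132 without triple mutant replicate 2 at 28 °C.

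**Figure D4:**
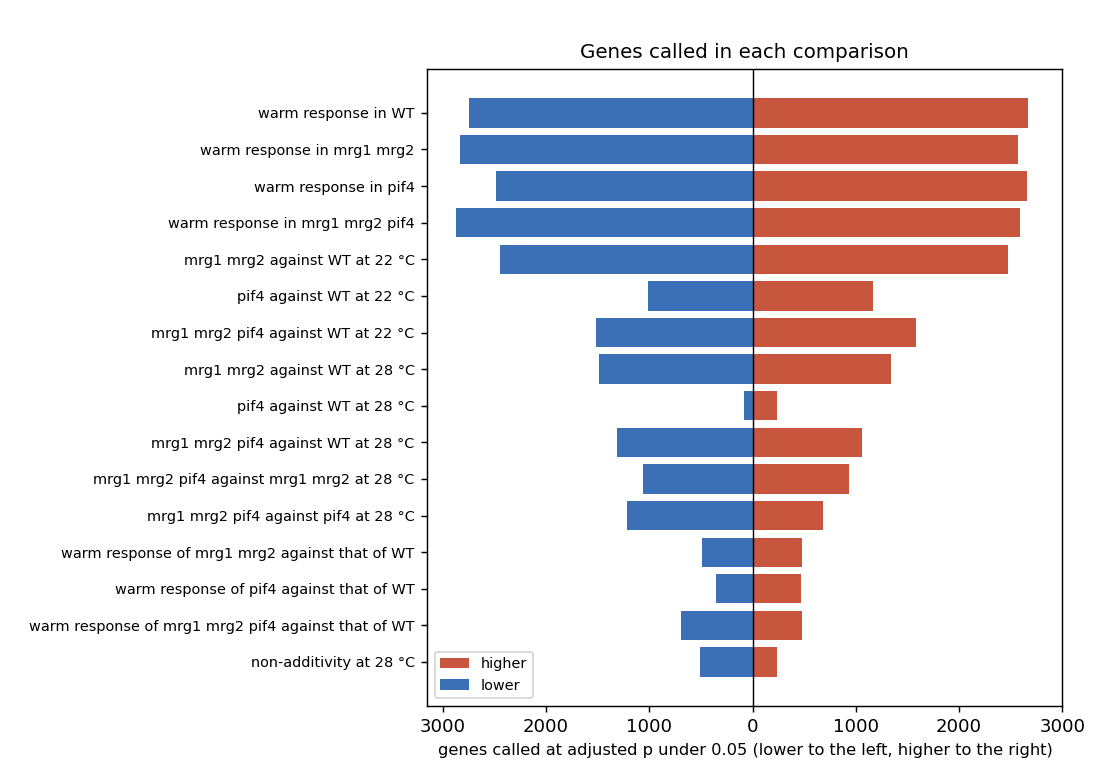
Number of genes that rose and fell (horizontal bars, adjusted p under 0.05 by edgeR) in each of the 16 comparisons. The warm response of WT holds 2666 and 2742 genes, and pif4 against WT at 28 °C holds 235 and 85.

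Whether the warm responses themselves differed was tested gene by gene as interactions. Cell division and photosynthesis genes responded less positively to warmth in every mutant than in WT. HIK rose in WT by 0.54 ± 0.10 (adjusted p = 6.34e-05) and fell in mrg1 mrg2 by 0.56 ± 0.09 (1.44e-05), a difference of −1.1 ± 0.14 (9.09e-07). Its level at 22 °C was 24.9 ± 0.975 CPM in WT and 46.9 ± 2.38, 46.5 ± 0.703 and 37.2 ± 3.14 in mrg1 mrg2, pif4 and the triple mutant. In mrg1 mrg2, 475 genes responded more positively and 490 more negatively than in WT, with the cell cycle list (0 up and 5 down of 11, 0 and 7 adjusted over the list alone; camera adjusted p = 2.32e-06) and the photosynthesis list (0 and 16 of 23, 0 and 20 adjusted over the list alone; 2.79e-38) both lower. PORB differed by −0.67 ± 0.07 (5.94e-09) and KIN2 by 0.91 ± 0.14 (2.95e-05). Of 11 cold response genes 2 differed upward and 1 downward (3 and 1 adjusted over the list alone; camera adjusted p = 0.0462, range 0.0397 to 0.145, adjusted p = 0.145 with an estimated correlation). This call was lost without any 1 library other than WT at 22 °C replicate 2, up to 0.139. PIF4-linked genes differed in 0 cases upward and 1 downward of 19 (camera adjusted p = 0.859), the median of the list being 0.027 and its mean and test lying below 0. The total of 965 genes was 618 and 600 without WT at 22 °C replicate 1 or 2, and 604 and 629 without mrg1 mrg2 at 22 °C replicate 1 or 2.

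In pif4, 471 genes responded more positively and 354 more negatively to warmth than in WT. PIF4-linked genes differed downward in 3 of 19 cases and upward in 0 (0 and 5 adjusted over the list alone; camera adjusted p = 0.00034). HIK differed by −1.01 ± 0.14 (adjusted p = 5.12e-06), AT5G02540 by −1.77 ± 0.23 (1.63e-06), F3H by 0.84 ± 0.13 (2e-05), CHS by 0.55 ± 0.08 (2.47e-05) and CRA1 by 3.77 ± 0.47 (8.38e-07). Cell cycle genes (0 up and 3 down of 11, 0 and 6 adjusted over the list alone; camera adjusted p = 3.65e-06), photosynthesis genes (0 and 13 of 23, 0 and 16 adjusted over the list alone; 4.9e-27) and unfolded protein response genes (0 and 1 of 11, 0 and 6 adjusted over the list alone; 0.00034) differed downward as lists. Seed storage genes (2 and 0 of 6, 3 and 0 adjusted over the list alone; 3.88e-05) and touch and wounding genes (1 and 0 of 21, 7 and 0 adjusted over the list alone; 0.00034) differed upward. So did root markers (4 and 0 of 22, 5 and 0 adjusted over the list alone; 0.0352, range over the alternatives 0.0135 to 0.0771, adjusted p = 0.0771 with an estimated correlation), a call lost without replicate 2 of WT (0.0579) or of pif4 (0.0711) at 28 °C. The total of 825 genes was 545 and 532 without WT at 22 °C replicate 1 or 2, 456 without pif4 at 22 °C replicate 2, 535 without WT at 28 °C replicate 2 and 549 without pif4 at 28 °C replicate 1.

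In mrg1 mrg2 pif4, 475 genes responded more positively and 696 more negatively to warmth than in WT. The antenna gene LHCB3 (AT5G54270) differed by −0.65 ± 0.07 (adjusted p = 7.52e-09), EXPA8 by −0.77 ± 0.11 (7.11e-06), HIK by −1.05 ± 0.14 (2.2e-06) and AT5G02540 by −2.23 ± 0.23 (9.85e-09). AT4G01870 and CYP81D11 (AT3G28740), a cytochrome P450 gene induced by foreign compounds, differed by 2.48 ± 0.18 (5.08e-12) and 2.19 ± 0.18 (1.03e-10). Of 23 photosynthesis genes 0 differed upward and 20 downward (0 and 20 adjusted over the list alone; camera adjusted p = 9.82e-63), and of 11 cell cycle genes 0 and 4 did (0 and 6 adjusted over the list alone; 4.58e-05). PIF4-linked genes differed downward in 1 of 19 cases and upward in 0 (0 and 1 adjusted over the list alone; 0.0133, adjusted p = 0.0641 with an estimated correlation). Root markers differed upward in 3 of 22 cases and downward in 0 (5 and 0 adjusted over the list alone; 0.0133, adjusted p = 0.0641 with an estimated correlation).

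Whether the effects of mrg1 mrg2 and of pif4 add at 28 °C was tested as the triple mutant's departure from their sum on the log2 scale. Both effects are measured against the same WT libraries at 28 °C. A departure of that WT group would therefore also appear as non-additivity, and the test cannot tell these apart. Photosynthesis genes lay below the sum and several xyloglucan enzyme genes above it. Xyloglucan enzyme genes were not tested as a list of their own. The cell wall list, to which XTH15 belongs, passed narrowly (camera adjusted p = 0.0437, adjusted p = 0.28 with an estimated correlation). Its call was also lost when any of 6 libraries was left out. XTH15 departed by 1.18 ± 0.15 (adjusted p = 2.03e-06). Its difference from WT was −0.80 in mrg1 mrg2 and −0.63 in pif4, and it stood at 37.4 ± 0.21 CPM in the triple mutant against 44.6 ± 0.703 in WT. XTH24 departed by 1.11 ± 0.09 (2.19e-11), XTH17 (AT1G65310) by 1.07 ± 0.21 (0.000965) and THA1 by 2.52 ± 0.24 (4.4e-09). DFR and LDOX departed by −2.35 ± 0.41 (0.000202) and −2.15 ± 0.39 (0.000417), and LHCB4.1 (AT5G01530) by −0.42 ± 0.06 (1.31e-05). In all 234 genes departed upward and 513 downward, and of 23 photosynthesis genes 0 and 20 did (0 and 21 adjusted over the list alone; camera adjusted p = 9.23e-55). The total of 747 genes was 484 without WT at 28 °C replicate 2 and 479 without triple mutant at 28 °C replicate 2.

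The genes that responded to warmth in WT were then followed in the mutants, to see how much of that response each kept. The 2666 genes that rose in WT had a median change of 0.457 in WT, 0.327 in mrg1 mrg2, 0.332 in pif4 and 0.309 in the triple mutant, and 88.5%, 89.6% and 85.9% of them lay above 0 in the mutants. By the interaction test the rise was smaller for 275, 202 and 353 of them and larger for 41, 21 and 20. The 2742 genes that fell had medians of −0.549 in WT, −0.348 in mrg1 mrg2, −0.331 in pif4 and −0.341 in the triple mutant, and their fall was smaller for 322, 354 and 354 and larger for 37, 24 and 74. Because genes picked in WT overstate the WT change, genes were also picked from WT replicate 1 alone. That removes only what is particular to replicate 1. A departure shared by both WT libraries of a group would still enlarge the change in WT replicate 2. The 216 that rose at least 2-fold there had medians of 1.21 in that replicate, 1.02 in WT replicate 2, and 0.897, 0.837 and 0.782 in mrg1 mrg2, pif4 and the triple mutant. The 344 that fell had −1.29, −1.15, −0.673, −0.614 and −0.663. The count of 275 was 181 or 160 without WT at 22 °C replicate 1 or 2, 180 or 176 without mrg1 mrg2 at 22 °C replicate 1 or 2 and 180 without WT at 28 °C replicate 1. The count of 202 was 133 without pif4 at 22 °C replicate 2, and the 354 in pif4 were 206 without that library and 222 without WT at 28 °C replicate 2.

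The effects of mrg1 mrg2 and pif4 at 28 °C were compared for shared genes. Of the genes that changed in both, 73 rose in both, 39 fell in both and 43 went opposite ways, where independent lists would share 16 and 6.29. Across genes, which are not independent replicates, the log2 changes of the mutants correlated at 0.399. This is below the mean of 0.541 for simulated unchanged mutants that shared simulated WT libraries, while the covariance was 0.0672 against a simulated 0.0456. In every simulation 0 genes rose in both, 0 fell in both and 0 went opposite ways. The simulations carry only the spread between libraries, not a departure common to both libraries of a group. A split would leave 1 WT library per comparison and was not made, so part of the sharing can come from the controls. The 73 genes were 25 without WT replicate 2, 44 without mrg1 mrg2 replicate 2, 46 without pif4 replicate 1 and 44 without pif4 replicate 2. The 39 were 21 without WT replicate 2 and 21 without pif4 replicate 1, and the correlation was 0.664 without WT replicate 1, all at 28 °C.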

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

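The tests of explanations in this part were chosen after the results they concern had been seen, while the interaction and additivity tests themselves were fixed before.

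MRD1 (AT1G53480), a gene named for its response in methionine-overaccumulating plants, was near silent in WT and on in every mutant library. WT libraries held 0 to 1 reads and mutant libraries 206 to 391, and at 22 °C the ratio of mutant to WT reads was 603 in mrg1 mrg2 (95% interval 108 to 23800), 490 in pif4 (87.5 to 19400) and 535 in the triple mutant (95.7 to 21200). Shallow WT libraries are excluded, since at the mutants' mean level the WT library with the fewest would hold 224 reads. A variant or silenced copy in the WT stock used here may underlie the difference, but of the 20 nearest tested genes only 1, the adjacent HEI10 (11 to 20 reads in WT libraries, 40 to 113 in the mutants), was called the same way in all 6 comparisons with WT, which leaves that open. HEI10 was lower in pif4 than in the triple mutant, with log2 differences of −0.73 ± 0.22 at 22 °C (adjusted p = 0.0322 by edgeR) and −0.67 ± 0.2 at 28 °C (0.0298). MRD1 was not called different between any of the mutants. That each mutation raises MRD1 on its own is open too: the triple mutant differed from pif4 by −0.03 on the log2 scale at 28 °C.

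The warm response of WT stood apart from that of all 3 mutants, with 965, 825 and 1171 genes called by the interaction tests, against 45, 86 and 103 between the mutants. Of 383 genes called in all 3, 382 differed in the same direction. Shared WT libraries alone produce such agreement in sign: at an unadjusted p under 0.05 in all 3, 99.6% had the same sign, and 99.4% in simulated unchanged mutants. They did not produce the number of calls, since the simulations called a mean of 0.1 genes in all 3, and at most 1. Over all genes tested, 60.5% had the same sign in all 3, against a simulated mean of 51%. The simulations carry only the spread between libraries. The covariances of the log2 differences were 0.159 to 0.167 against simulated means of 0.0809 to 0.0812, and deeper sequencing of WT is excluded, as its libraries averaged 8.35 M counts and those of the mutants 9.46 M. Of the 383 genes, 5.74% differed from WT in all 3 mutants at 28 °C, against 77.5% at 22 °C. This argues against a lack of the WT state at 28 °C common to all 3 mutants as the main account. The share is limited by pif4, with 320 genes called against WT at 28 °C, against 2830 in mrg1 mrg2 and 2377 in the triple mutant. It therefore cannot exclude such a lack in mrg1 mrg2 or in the triple mutant. The values are in line with a departure of the WT group at 22 °C, with a median distance of the mutants from WT 2.74 times that at 28 °C (0.538 against 0.197), but whether growth and handling of those WT plants or a biological effect of each mutation at 22 °C may produce it was not tested.

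PIF4 mRNA was not called lower than in WT in genotypes labelled pif4, with means of 27.9 CPM in pif4 and 38.3 in the triple mutant against 31.7 in WT at 22 °C, and 78.2 and 83.5 against 90.4 at 28 °C, where the triple mutant lay below mrg1 mrg2 by 0.33 on the log2 scale (adjusted p = 0.00828, lost without replicate 1 of either, at 0.0775 and 0.141). Every library of these genotypes held at least 206 MRD1 reads and WT libraries 0 to 1, so they do not share the near silence of MRD1 in WT. This would exclude plants of the WT stock used here only if that near silence is fixed in the stock, which was not tested. MRD1 cannot show whether plants of any other stock had PIF4 intact, since the cause of its difference is open. An allele that still makes transcript is a candidate explanation: PIF4-linked growth genes were lower at 28 °C in both genotypes labelled pif4, with a highest adjusted p of 0.00454 with an estimated correlation. The list was also lower in mrg1 mrg2 (0.00315; adjusted p = 0.0876 with an estimated correlation), and the triple mutant was not called lower than mrg1 mrg2 (0.0545), so its fall is not shown to be particular to the label pif4. Another mutant under the label stays open, since the labels give no allele.

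The warm response of mrg1 mrg2 differed from that of WT by the interaction test for UGT74E2 (3.52), XTH13 (2.54), KIN2 (0.91), HIK (−1.10), KN (−0.85), PORB (−0.67), RBCS1A (−0.36) and HSP90.7 (−0.40), all as log2 differences. The median difference was −0.72 over the cell cycle list and −0.26 over the photosynthesis list.

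The warm response of pif4 differed from that of WT upward for the seed genes CRU3 (5.05), M17 (4.76) and CRA1 (3.77), the root genes EXPA7 (1.58) and ESB1 (0.71), and the flavonoid genes F3H (0.84) and CHS (0.55). It differed downward for AT5G02540 (−1.77), HIK (−1.01), KN (−0.75), PORB (−0.45) and HSP90.7 (−0.41). Its list medians were 2.7 for seed storage, 0.44 for touch and wounding, −0.68 for cell cycle, −0.43 for PIF4-linked growth genes, −0.22 for photosynthesis and −0.2 for the unfolded protein response.

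The warm response of mrg1 mrg2 pif4 differed from that of WT upward for AT4G01870 (2.48), CYP81D11 (2.19) and KIN2 (0.73). It differed downward for AT2G43620 (−2.73), AT5G02540 (−2.23), HIK (−1.05), KN (−0.86), EXPA8 (−0.77), LHCB3 (−0.65), RBCS1A (−0.52) and HSP90.7 (−0.43). Its list medians were −0.68 for cell cycle and −0.47 for photosynthesis.

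In the additivity test, a departure of the WT group at 28 °C would also count as non-additivity, and this was not tested. At 28 °C 747 genes departed from the sum of the effects of mrg1 mrg2 and pif4. The triple mutant lay above their sum for the peroxidase gene AT2G39040 (2.80), THA1 (2.52), the arabinogalactan gene AGP30 (2.22), BCAT-2 of branched-chain amino acid metabolism (2.04), XTH15 (1.18), XTH24 (1.11) and XTH17 (1.07). It lay below for DFR (−2.35), LDOX (−2.15), LHCB4.1 (−0.42) and RBCS1A (−0.38), and the median over the photosynthesis list was −0.36.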

How the results depend on the processing

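All alternatives here were chosen beforehand except the fit without organelle and rRNA genes. Of 277 named gene results, 267 kept their direction and their side of the threshold under every alternative that gave a value, and 10 did not, 9 of them when a library was left out. Of the 10, PIF4 in mrg1 mrg2 pif4 at 22 °C lost its call under several alternatives: RLE gave an adjusted p of 0.0511, no filter 0.0622, legacy = TRUE 0.0518, only the compared groups 0.0535 and DESeq2 0.147 (range 0.0196 to 0.45). Differences that were not called reversed in pif4 at 28 °C: over the left-out libraries MRG1 ranged from −0.206 to 0.0829 and MRG2 from −0.226 to 0.0684. MRG1 was above 0 without WT at 28 °C replicate 2 (0.0282) or pif4 at 28 °C replicate 1 (0.0829), and MRG2 without the latter (0.0684). Of 108 list calls, 51 were kept with an estimated correlation, 106 with RLE, 100 with the replicate block, and 37 were lost without at least 1 library, none of them among the 51. By the limit of 0.1 for every pair of groups, replicate numbers were not taken to pair the libraries: over 28 pairs of groups, the deviations of same-numbered libraries correlated at −0.0098 to 0.068. Some variation does go with the number: the AT3G41768 share and the third principal component put the replicates in the same order in all 8 groups. Among the 4015 most expressed genes, chosen after the data had been seen, the correlations ran from −0.11 to 0.56 (median 0.23), with 24 of 28 over 0.1. With the replicate block no named gene changed its call, and 8 list calls were lost: cell cycle in the WT warm response (0.0529), heat shock (0.0568), light signalling (0.0546) and PIF4-linked genes (0.0668) in mrg1 mrg2 at 22 °C, heat shock (0.0513), anthocyanin (0.0603) and seed storage (0.0603) in mrg1 mrg2 at 28 °C, and anthocyanin in non-additivity (0.061).

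DESeq2 counted fewer genes, by more than 1.5 times, in 8 comparisons, and the cause was not tested: pif4 22 °C 1404, mrg1 mrg2 pif4 22 °C 1981, mrg1 mrg2 28 °C 1774, mrg1 mrg2 pif4 28 °C 1440, mrg1 mrg2 pif4 against mrg1 mrg2 1271 and against pif4 1156, and the warm response differences of mrg1 mrg2 632 and of pif4 536. Of the medians of WT-responsive genes, RLE moved that of the risen in pif4 to 0.325 and of the fallen in mrg1 mrg2 to −0.345. The replicate block moved those of the risen to 0.449 in WT, 0.313 in mrg1 mrg2, 0.322 in pif4 and 0.301 in the triple mutant, and of the fallen in mrg1 mrg2 to −0.341. All stayed on their side of 0, and the cause was not tested.

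With each library left out in turn, where a lone library is taken to vary like the other groups, the warm responses held 3953 to 5498 genes in WT, 3838 to 5485 in mrg1 mrg2, 3532 to 5176 in pif4 and 3807 to 5543 in the triple mutant. Against WT at 22 °C, mrg1 mrg2 gave 3306 to 5022, pif4 1234 to 2276 and the triple mutant 1957 to 3157. At 28 °C they gave 1570 to 2895, 150 to 354 and 1402 to 2454. The triple mutant gave 1060 to 2071 against mrg1 mrg2 and 1090 to 1942 against pif4. The interactions gave 600 to 985 in mrg1 mrg2, 456 to 872 in pif4 and 826 to 1224 in the triple mutant, and non-additivity 479 to 749. List calls numbered 92 to 109. Medians of risen genes were 0.456 to 0.544 in WT, 0.324 to 0.362 in mrg1 mrg2, 0.312 to 0.366 in pif4 and 0.298 to 0.343 in the triple mutant. Those of fallen genes were −0.618 to −0.549, −0.382 to −0.347, −0.37 to −0.329 and −0.388 to −0.337. Smaller rises numbered 160 to 282, 133 to 238 and 252 to 382 in the mutants, and smaller falls 215 to 335, 206 to 364 and 239 to 361. Genes shared by mrg1 mrg2 and pif4 at 28 °C numbered 25 to 82 up and 21 to 39 down, and their correlation was 0.295 to 0.664. In simulated data, 40% of 1.5-fold and 74% of 2-fold changes were recovered in the WT warm response, which limits what an uncalled gene shows.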

Other observations

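The comparisons between the warm responses of the mutants and the genes on or off in single genotypes were looked for after the data had been seen.

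Some genes of detoxification and chemical stress, picked after their values were seen and not tested as a group, stood higher in WT at 22 °C than in the mutants. AT4G01870 stood at 113 ± 5.17 CPM (SD, n = 2) in WT at 22 °C and at 24.7, 17.3 and 25.4 in mrg1 mrg2, pif4 and the triple mutant, with 12.4 in WT at 28 °C. CYP81D11, which responds to foreign compounds, stood at 72.2 ± 1.17 CPM against 16.2, 20 and 15, with 14.3 in WT at 28 °C. GSTU24, a glutathione transferase gene, stood at 38.7 ± 6.15 CPM against 22.6, 16.2 and 13.9, and UGT74E2 at 16 ± 1.29 against 4.57, 3.6 and 3.25. ChlAKR, an aldo-keto reductase gene of the chloroplast, stood at 5.34 ± 0.552 CPM against 0.702, 0.162 and 0.958, and UGT73C1 at 5.54 ± 0.26 against 0.525, 0.455 and 0.64. The 0.162 CPM of ChlAKR in pif4 lies below the floor of 0.296 to 0.353 CPM of those libraries.

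FLC and MAF5, 2 flowering repressor genes, were followed singly. FLC, which delays flowering until after winter, stood at 9.31 ± 1.21 CPM in WT and 4.69 ± 0.427 in mrg1 mrg2 pif4 at 22 °C (log2 change −0.98 ± 0.22, adjusted p = 0.00155 by edgeR), and at 9.25 ± 1.05 and 3.29 ± 0.295 at 28 °C (−1.49 ± 0.24, 2.51e-05). Against pif4 at 28 °C, with 12.2 ± 0.339 CPM, FLC in the triple mutant fell by 1.87 ± 0.23 (1.36e-07). Its relative MAF5 fell in mrg1 mrg2 at 22 °C by 1.77 ± 0.42 (0.00135). The flowering list did not pass in mrg1 mrg2 (1 up and 2 down of 13, 1 and 2 adjusted over the list alone; camera adjusted p = 0.293) or the triple mutant (0 and 2, 0 and 2 adjusted over the list alone; 0.904) at 22 °C, nor in the WT warm response (2 up and 4 down of 13, 2 and 5 adjusted over the list alone; camera adjusted p = 0.742).

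AT2G01422 and AT1G63540 held more reads in pif4 than in other genotypes. AT2G01422 held 316 reads in pif4 at 22 °C against 0 in WT, at least 101-fold higher with a floor of 3 reads over the group, and 218 against 5 at 28 °C, a ratio of 38.1 (95% interval 16.1 to 118). AT1G63540, for a hydroxyproline-rich protein, held 93 reads against 0 at 28 °C, at least 27.1-fold higher with the same floor, and 55 against 1 at 22 °C, a ratio of 52.5 (9.04 to 2110). The triple mutant held 1 to 5 reads of either gene per temperature, and mrg1 mrg2 at 28 °C 11 and 6, all in replicate 2. Seed storage reads were high in pif4 at 28 °C in both libraries, with 289 to 406 of CRA1 against at most 48 in any other library, and 214 to 250 of CRU3 against at most 20. In mrg1 mrg2 at 28 °C they numbered 24 and 12 in replicate 2 against 2 and 0 in replicate 1, and the cause was not tested.

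In all 6 comparisons of a mutant with WT, which share WT libraries, 25 genes (0.125% of those tested) changed in the same direction. Their number cannot exceed the 320 genes called in pif4 against WT at 28 °C, the fewest of the 6. The 25 genes include the chlorophyll synthesis genes PORB and HEMC and the antenna genes LHCB2.2 and LHCB2.3 (up), and IAA2, KCS1 for wax synthesis and VTC2 for vitamin C synthesis (down).

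The same edgeR test called fewer differences among the mutants' warm responses: 45 genes between pif4 and mrg1 mrg2, 86 between the triple mutant and mrg1 mrg2, and 103 between the triple mutant and pif4, with 1580, 1672 and 1871 at an unadjusted p under 0.05.

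Other lists did not pass in the WT warm response. Salicylic acid defence genes rose in 1 of 14 cases and fell in 3 (1 and 4 adjusted over the list alone; camera adjusted p = 0.151), and abscisic acid genes rose in 2 of 13 and fell in 3 (2 and 4 adjusted over the list alone; 0.692). Chromatin factor genes rose in 4 of 22 cases and fell in 1 (4 and 1 adjusted over the list alone; 0.353), and shoot meristem and epidermis markers rose in 2 of 13 and fell in 0 (1 and 0 adjusted over the list alone; 0.251). Auxin biosynthesis genes rose in 3 of 9 cases and fell in 2 (3 and 2 adjusted over the list alone; 0.692), with a median of 0.22 and a test that pointed down. Light signalling genes rose in 5 of 18 cases and fell in 5 (7 and 6 adjusted over the list alone; 0.742), with a median of 0.057 and a mean of −0.004.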
